A study of Drosophila melanogaster with 2 samples.

How the data were processed

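Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos collected 0 to 24 hours after laying, from transgenic flies that carry the protein encoded by wings down (wdn) fused to eGFP. Per the labels, chromatin was fragmented by sonication to a size range of 200 to 800, and the fusion protein was recovered with an antibody against GFP. The 2 samples were biological replicates 1 and 2 of a single group. The labels named a possible control library, which was not analysed here, so no sample served as a control.

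The deposited data were peak lists on the dm6 build, per the file headers. For both replicates together there were 2 thresholded lists, 1 of them named conservative, each with its ranked list, and every replicate had 1 thresholded and 1 ranked list of its own. All were made with the irreproducible discovery rate (IDR), which compares the ranking of peaks between data sets. The text deposited with the lists stated that a thresholded list derived from the same inputs as its ranked list and from 1 further file. The aligner, the peak caller and their versions were not given in the sources used here. The signal value of each peak was the authors' own, given by their peak caller, and what it is relative to was not stated. It was used only to describe and rank peaks within a list and, for the agreement of the replicates, to correlate log2 signal over shared peaks. The deposited IDR score rises as IDR falls and is capped at 1000. The deposited ranked lists also gave the -log10 of the global IDR, capped at 5. In all 4 pairs of lists every thresholded peak was present in its ranked list with a global IDR of at most 0.01. Further columns of the ranked lists hold 2 sets of per-sample values with no sample label and were not used.

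The thresholded list from both replicates that is not named conservative was the main list. Ranked peaks outside a thresholded list, called candidates below, served as the background, since only they could have entered it. Summits were placed on the Ensembl release 115 annotation of the same assembly, with 18277 genes on chromosomes X, 2L, 2R, 3L, 3R, 4 and Y and annotated transposable element copies kept apart. Chromosome lengths of the reference held every peak of the lists. A summit within 500 bp of an annotated transcript start was a promoter summit. Other summits were assigned, in this order, to 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic sequence. A gene was called bound when a main-list summit lay within 500 bp of one of its starts.

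Shares were tested with two-sided Fisher's exact tests against candidates and carry 95% exact binomial (Clopper-Pearson) intervals. Adjusted p-values are Benjamini-Hochberg values over the 7 genomic classes, 8 chromosome groups, 23 gene lists, 13 consensus motifs or 10 words of a family. The lowest p computed was 1e-300. All p-values are over peaks or genes, which are not replicates, and neighbouring genes can share a peak. Gene lists were compared with all other genes that had a ranked peak within 500 bp of a start. Of the list members looked up by symbol, 4 were matched by hand to the annotation's own symbol. Motifs and words were searched on both strands within 50 bp of the summit, against 5 candidates per peak with the same promoter share. Words of 8 bases were ranked on X, 2L and 2R among those in at least 30 peaks, and the best 10 were tested on 3L and 3R.

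The genes named were fixed by rule. These are wdn, then the genes with the strongest main-list summits within 500 bp of a start until 25 were reached, with both genes named for a pair of diverging starts. The last such pair brought the number to 26. Up to 4 bound members of each gene list with the highest signal were eligible, or up to 2 members with the lowest candidate IDR where none was bound. The 5 strongest peaks outside promoters completed the rule. The tests, gene lists, motifs, named-gene rule and the first set of alternatives were set before the data were examined.

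Alternatives covered the conservative list, a stricter IDR, each replicate's own list, other promoter windows, overlap rules and backgrounds. The stricter IDR of 0.01 set then removed no peak, and an IDR of 0.001 was added after seeing the data. Also added then were backgrounds matched on GC content in classes of 4 percentage points, a word search within 200 bp of the summit, assignment of each peak to its nearest start, and inclusion of passing candidates that the main list lacks.

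The tests were tested on simulated data made by drawing 3000 peaks from the real candidates. A promoter odds ratio of 4 was recovered with a median of 4.14 over 5 draws, a list with raised odds was called in 5 of 5 draws, and none of 110 tests of the other lists was called. Both 8-base words placed into the windows were among those called, and with nothing placed 0 of 10 words and 0 of 13 motifs were called. Simulated peaks came from the candidates, so they shared the base composition of their background, which the real peaks did not. The simulation therefore cannot show how the word and motif tests behave under that difference. Weaker effects than those placed were not tried. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Read depth per sample was not part of the lists analysed here, so depth is unknown and the intervals cover counting of peaks only.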

Results

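The genome-wide binding of Wdn, a C2H2 zinc finger protein, was measured in Drosophila embryos by ChIP-seq of a Wdn-eGFP fusion. There was 1 group of 2 biological replicates, so the comparisons were between replicates and between peaks and the candidates that were ranked but not listed. The main list, made from both replicates, held 3254 peaks, 2.46% of 132052 ranked peaks. Peaks had a median width of 304 bp and a median signal value of 76.6, with a highest value of 1483. Alone, replicate 1 gave 1996 peaks and replicate 2 gave 1796, or 1896 ± 141 (SD, n = 2). The conservative list held 2722 peaks.

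The 2 replicates placed most of their peaks at the same sites. Of the replicate 1 peaks, 1279 (64.1%, 95% interval 61.9 to 66.2%) overlapped a replicate 2 peak by at least 1 base, against 0.821% of its 68781 candidates (odds ratio 215, Fisher's exact test, p = 1e-300). Of the replicate 2 peaks, 1276 (71.0%, 68.9 to 73.1%) overlapped a replicate 1 peak, against 0.839% of 83405 candidates (odds ratio 290, exact p = 1e-300). Across the 1279 shared peaks, which are not independent replicates, the signal values of the replicates had a Spearman rho of 0.75 and a Pearson r of 0.75 on the log2 scale. Over all 39622 shared ranked peaks, listed or not, the rho was 0.32. In the main list, 1273 peaks (39.1%) were found in both replicates' own lists, with a median signal of 133 (quartiles 103 and 200). The 944 peaks (29.0%) found in neither had a median of 55.0 (49.7 and 61.5).

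**Figure D1:**
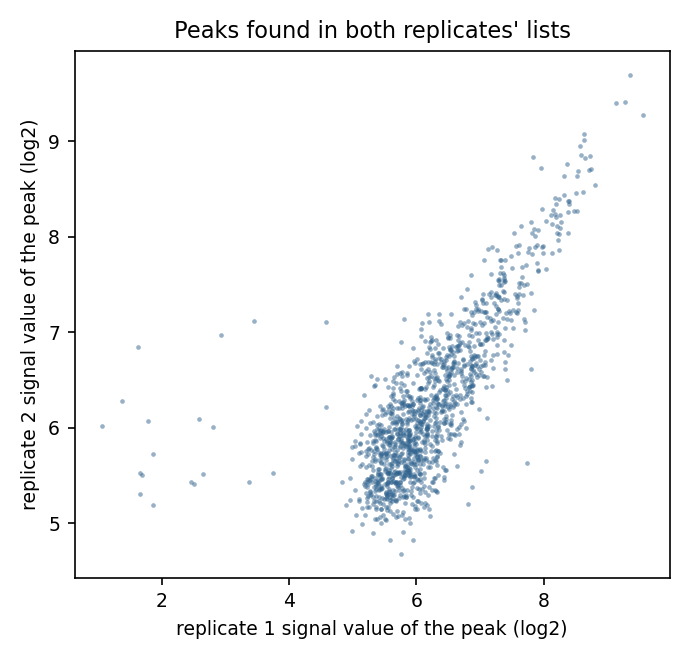
Signal value of each of the 1279 shared peaks in replicate 1 (x axis, log2) and replicate 2 (y axis, log2). Each point is a peak, and the points rise together with a Spearman rho of 0.75.

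Wdn peaks lay mainly at gene promoters, a short distance upstream of the start. Of 3248 summits on the chromosome arms and chromosomes 4 and Y, 1705 (52.5%, 50.8 to 54.2%) were within 500 bp of an annotated start, against 15.5% of 127248 candidates (odds ratio 6.01, Fisher's exact test, p = 1e-300). The replicates' own lists gave 56.8% ± 1.49 (SD, n = 2). The share was 67.0% (62.7 to 71.1%) among the strongest 500 peaks, 54.8% (51.7 to 57.9%) among the next 1000 and 47.0% (44.7 to 49.4%) in the remaining 1748. Promoter summits had a median position of -95 bp relative to the nearest start (quartiles -174 and -16), and 1327 of the 1705 (77.8%) were upstream. Candidates at promoters had a median of 66 bp, with 40.9% upstream (odds ratio 5.06, Fisher's exact test, p = 3.78e-195).

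**Figure D2:**
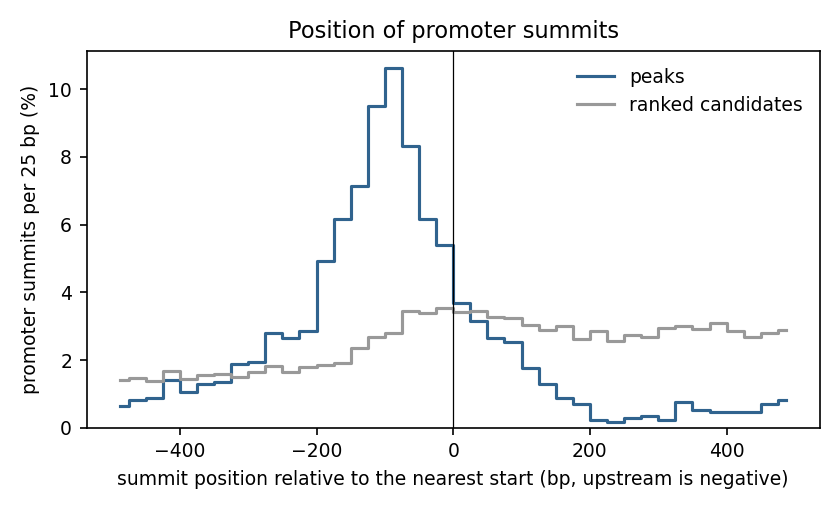
Position of promoter summits relative to the nearest transcript start (x axis, bp) for main-list peaks and candidates, as the percentage of promoter summits in each 25 bp step (y axis). Peaks concentrate upstream of the start, with a median of -95 bp, and candidates have a median of 66 bp.

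Exons held few Wdn peaks. Coding exons contained 48 summits (1.48%, 1.09 to 1.95%) against 20.6% of candidates (odds ratio 0.0580, adjusted exact p = 1.48e-241), and 3' UTRs held 25 (0.770%) against 2.92% (odds ratio 0.258, adjusted exact p = 4.37e-17). Intergenic sequence held 348 (10.7%) against 22.1% (odds ratio 0.423, adjusted exact p = 2.00e-62). Introns, the second largest class, held 1076 (33.1%) against 37.1% (odds ratio 0.841, adjusted exact p = 5.81e-06). The 17 summits in 5' UTRs beyond the promoter window (0.523%) compared with 1.00% of candidates (odds ratio 0.520, adjusted exact p = 0.00599), a call that was lost against random positions (adjusted exact p = 0.109) and with the passing candidates that the main list lacks added (0.0598). The coding exon odds ratio was 0.0139 in replicate 2's own list, 0.0109 in that of replicate 1, 0.0116 at an IDR of at most 0.001, 0.0252 in the conservative list and 0.0936 against random positions. The odds ratio of 5' UTRs was 0.249 in replicate 1's own list and that of 3' UTRs 0.166 against random positions. Other exons, at 0.893% and 0.832%, did not pass the test (adjusted exact p = 0.695). Each summit had 1 class, promoters first, so the promoter excess lowers every other share. Outside promoters, introns held 1076 of 1543 peak summits and 47157 of 107474 candidates, a larger share of peaks. Counts were 17 and 1275 for 5' UTRs, 348 and 28103 for intergenic sequence, and 48 and 26159 for coding exons. The intron and 5' UTR deficits can thus restate the promoter excess, and shares outside promoters were not tested.

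**Figure D3:**
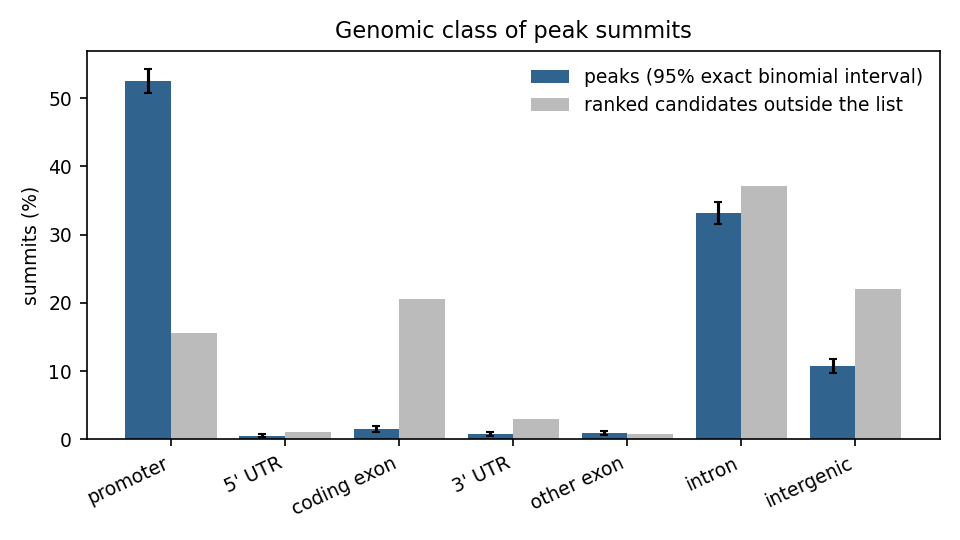
Percentage of summits in each genomic class (y axis) for 3248 main-list peaks, with 95% exact binomial intervals, and 127248 candidates. Promoters hold 52.5% of peaks and 15.5% of candidates, and coding exons 1.48% and 20.6%.

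Among the large chromosome arms only 3R differed from the candidates. Arm 3R held 741 peaks (22.8%) against 24.9% of candidates (odds ratio 0.891, Fisher's exact test, adjusted p = 0.0157), and X, 2L, 2R and 3L did not pass the test. The 3R call was lost in the conservative list (odds ratio 0.900, adjusted exact p = 0.0592), against chromosome length (exact binomial test, adjusted p = 0.507) and with the passing candidates that the main list lacks added (odds ratio 0.940, adjusted p = 0.336). The deficit was larger in replicate 1's own list (odds ratio 0.790, adjusted exact p = 0.000143) and in that of replicate 2 (0.802, 0.000416). At an IDR of at most 0.001 it also passed (0.815, 0.0022). The X held 581 peaks (17.9%) against 17.6% (adjusted exact p = 0.831). Its odds ratio rose to 1.37 in replicate 2's own list (adjusted exact p = 2.81e-06), 1.19 in that of replicate 1 (adjusted exact p = 0.00940) and 1.19 at an IDR of at most 0.001 (adjusted exact p = 0.0114). Of the 121 passing candidates that the main list lacks, 3R held 59 and X held 2. In replicate 1, 72 of the 121 overlapped a passing candidate that its own list also lacks, and in replicate 2, 58 did. Such candidates were added back to the main list only, so the replicates' 3R and X values share this gap. Chromosome 4 held 4 peaks (adjusted exact p = 1), fewer than its length would give (ratio 0.125, exact binomial test, adjusted p = 4.15e-09). No main-list peak lay on the Y, against 266 candidates (adjusted exact p = 0.00943, not past the threshold in either replicate's own list or, at 0.109, at an IDR of at most 0.001). Other scaffolds held 6 against 1550 (odds ratio 0.152, adjusted exact p = 9.31e-10), a call lost in replicate 2's own list (odds ratio 0.706, adjusted exact p = 0.628). The scaffold odds ratio was 0.0661 in the conservative list, 0.0980 at an IDR of at most 0.001 and 0.343 with the missing passing candidates added, and no scaffold peak was in replicate 1's own list.

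The wdn gene itself (3R, 28807983 to 28811337, minus strand) had no main-list peak within 500 bp of its start at 28811337. The 2 candidates in that window had summits at 28811048 and 28811373, with global IDR values of 0.244 and 0.598. A candidate with a signal of 61.5 and an IDR of 0.0347 had its summit at 28812007, 670 bp upstream of the wdn start and 95 bp from the start of Prp39. The nearest main-list summit was 8409 bp from the wdn start. Whether the tagged transgene affects mapping at this locus was not tested, so the absence of a peak there does not show an absence of binding.

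The strongest promoter peaks of the main list included peaks within 500 bp of starts of 3 mitochondrial ribosomal protein genes. Many were shared by a pair of diverging starts, among them those of mRpS10 and mRpS23, which lay nearer to the other gene's start. The strongest of all was 94 bp upstream of CG14100 (FBgn0036889), with its summit at 19590618 on 3L and a signal of 1483. Its replicate values were 655 and 829. Next was Ugalt (FBgn0024994), a UDP-galactose transporter gene, with a summit at 2703897 on X, 45 bp upstream of the start, and a signal of 1300 (replicates 623 and 680). The mitochondrial ribosomal protein gene mRpL41 followed, with a summit at 15217764 on 2R, 147 bp upstream of the start, and a signal of 1224 (561 and 676). The sequence around the CG14100 summit, 3L from 19590568 to 19590668, read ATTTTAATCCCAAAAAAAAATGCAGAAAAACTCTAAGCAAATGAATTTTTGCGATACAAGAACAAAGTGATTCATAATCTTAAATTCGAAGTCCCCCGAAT and was 70.3% A and T.

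Of the pairs with diverging starts, CG7601 and CIA30, a gene for an assembly factor of respiratory complex I, shared a summit at 29736846 on 3R with a signal of 937. The summit at 23850404 on 2R (signal 908) was shared by eIF6, a factor in ribosome biogenesis, and asRNA:CR45928, 103 bp upstream of the first and 74 bp downstream of the second start. Art3, an arginine methyltransferase gene, and mRpS10 shared a peak of signal 879 at 15229532 on 3R. It lay 124 bp upstream of the Art3 start and 133 bp upstream of the mRpS10 start. CG5611 and Mtl shared a peak of 876. The peak of CenG1A and mRpS23 had a signal of 858. Tcs5 and CHMP2B, an ESCRT-III component gene, shared one of 845. Weaker pairs were CG8320 with Pex11ab (745), CG13390 with CG17294 (745) and Atat with Shc (670). Single genes in this group were ph-p (827), which encodes a Polycomb repressive complex 1 subunit, PNPase (812), lncRNA:CR44619 (746), CG18549 (725) and px (673). All 26 genes were also bound in the conservative list and in replicate 1's own list, and all but ph-p, whose summit was at -498 bp, in that of replicate 2.

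The 5 strongest main-list peaks outside promoters were intronic. The first lay in CG11050, with its summit at 6612706 on 2L, 1019 bp from the nearest start, and a signal of 1372 (replicates 752 and 617). An intron of CG32772 held a peak of signal 859 at 4910374 on X. Adf1 and Trl, which both encode DNA-binding transcription factors, held intronic peaks of 770 at 6663042 on 2R and of 725 at 14759507 on 3L. A peak of 687 at 21703397 on 2R lay 567 bp from a start of HmgZ, within both HmgZ and its neighbour HmgD, which encode HMG-box proteins.

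Cytosolic ribosomal protein genes were bound far more often than other genes. Of 88 with a candidate, 58 (65.9%, 55.0 to 75.7%) were bound, against 15.4% of 14309 other genes (odds ratio 10.7, Fisher's exact test, adjusted p = 5.49e-25). Without replicate 1, 43 of 86 were bound (odds ratio 6.79), and without replicate 2 the odds ratio was 7.43. Genes whose passing peak the main list lacks count as not bound here, and with those peaks added 59 of 88 were bound (odds ratio 10.9) and no gene list changed its side of the threshold. Genes with the symbol prefix RpL accounted for 35 of 50 and those with RpS for 22 of 37, and sta, also in the list, carries neither prefix. The strongest were RpL7 (signal 366, summit 33 bp downstream of the start), RpL34b (319), RpS27 (260) and RpL23A (221). Bound ribosomal protein genes had a median signal of 85.1 (quartiles 75.4 and 122), and the other bound genes 87.3 (63.3 and 140). The other housekeeping lists did not pass the test. These were mitochondrial ribosomal proteins (16 of 63 bound, adjusted exact p = 0.136), oxidative phosphorylation (16 of 67, 0.171), aminoacyl-tRNA synthetases (8 of 30, 0.221), translation initiation factors (8 of 38, 0.600) and the proteasome (4 of 40, 0.600). Oxidative phosphorylation came past the threshold with a 200 bp window (adjusted exact p = 0.0323) and mitochondrial ribosomal proteins against all annotated genes (adjusted exact p = 0.0489).

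Genes for chromatin architecture were also bound above the background. Of 17 insulator and architectural protein genes, 9 (52.9%, 27.8 to 77.0%) were bound (odds ratio 6.08, adjusted exact p = 0.00188), among them Chro (669), Cp190 (271), Trl (191) and Dref (118). Polycomb and trithorax group genes were bound in 8 of 21 cases (odds ratio 3.32, adjusted exact p = 0.0309), with brm at 368 and E(z) at 193. Trl belongs to both lists. Germ line and maternal genes (10 of 24, odds ratio 3.86, adjusted exact p = 0.00789) included orb at 160 and plu at 88.0. Cell cycle and DNA replication genes (11 of 29, odds ratio 3.30, adjusted exact p = 0.00995) included RnrS at 195 and Dp at 168. The insulator odds ratio was 13.3 in replicate 2's own list, and the call was lost in that of replicate 1 (odds ratio 3.07, adjusted exact p = 0.175) and when each peak was assigned to its nearest start (adjusted exact p = 0.101). The germ line, cell cycle and Polycomb calls were lost in both replicates' own lists and at an IDR of at most 0.001, and the Polycomb call also in the conservative list (adjusted exact p = 0.273) and with windows of 200 bp (0.233) and 1000 bp (0.0707).

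No list of regulators or markers of embryonic tissues passed the test. Bound were 4 of 30 segmentation and homeotic regulators (adjusted exact p = 1), including nkd (139) and ptc (78.7), and 4 of 24 dorsoventral and germ layer regulators (0.905), including tin (135) and fkh (101). Neurogenic genes were bound in 3 of 25 cases (0.905), with numb at 219, neuron markers in 2 of 19 (0.905), with elav at 323, and glia markers in 2 of 12 (adjusted exact p = 1), with moody at 490. Muscle markers were bound in 4 of 26 cases (adjusted exact p = 1), with Msp300 at 302, and hemocyte and fat body markers in 1 of 15 (0.707), ush at 82.2. Sex determination and dosage compensation genes (5 of 26, 0.797), heat shock and chaperone genes (7 of 23, 0.160, with Hsp27 at 311) and piRNA pathway genes (7 of 22, 0.158) did not pass the test.

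Of the 23 lists, 3 were bound less often than other genes. None of 87 cuticle protein genes was bound (upper limit of the 95% interval 4.15%, adjusted exact p = 8.22e-06), the best candidate being at Edg78E with an IDR of 0.0489, and 1 of 107 was with a 1000 bp window. Chemosensory receptor genes (odorant and gustatory, and ionotropic ones, which the list also held) were bound in 2 of 117 cases (odds ratio 0.0928, adjusted exact p = 8.39e-06), Ir60e and Gr63a, and in none in either replicate's own list or at an IDR of at most 0.001. Of 208 tRNA genes, 12 were bound (odds ratio 0.326, adjusted exact p = 0.000107), and neighbouring copies such as tRNA:Asp-GTC-1-4 and tRNA:Asp-GTC-1-5 shared a peak. The tRNA odds ratio was 0.111 in replicate 2's own list, 0.134 with a 200 bp and 0.490 with a 1000 bp window, 0.151 with nearest starts and 0.215 in the conservative list. In all, 2255 of 14397 genes with a candidate were bound, 2087 of them protein-coding.

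**Figure D4:**
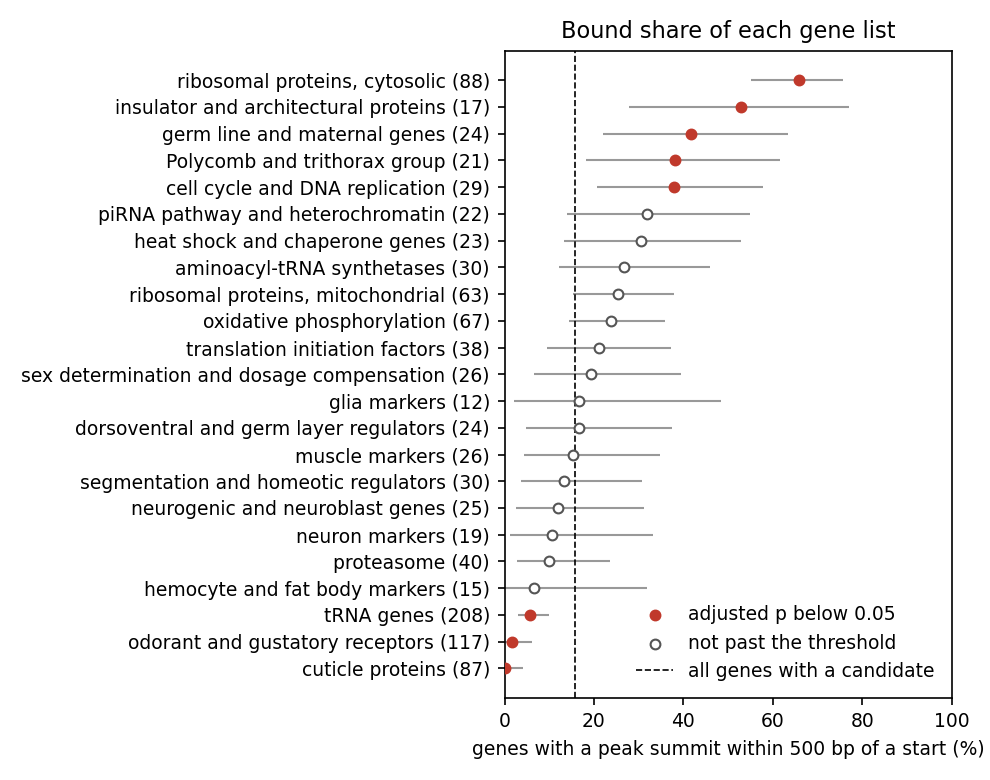
Percentage of each gene list bound by Wdn (x axis), with 95% exact binomial intervals and the number of genes tested in brackets (y axis labels). Cytosolic ribosomal proteins stand at 65.9%, and the dashed line marks the share over all 14397 genes with a candidate.

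Peak summits were rich in A and T. The sequence within 50 bp of main-list summits held 63.5% A and T (SD 10.8, n = 3248 peaks) against 53.1% (SD 9.79) in 16240 matched candidates, and the strongest 500 held 69.2% (SD 8.70). The rise over the sequence 500 bp away was 6.64 ± 0.245 percentage points (standard error) in the main list, and it was 7.70 ± 0.314 in replicate 1's own list and 10.3 ± 0.305 in that of replicate 2. All 10 words carried forward from X, 2L and 2R consisted of A and T alone and passed the test on 3L and 3R. TTAAAAAA was in 86 of 1430 peaks (6.01%) against 1.49% of candidates (odds ratio 4.24, Fisher's exact test, adjusted p = 1.08e-19), and TATATTAA in 2.94% against 0.605% (odds ratio 4.97, adjusted p = 2.81e-12). With the peaks' own flanks 500 bp away as background, both odds ratios were lower. They were 2.84 for TTAAAAAA (adjusted exact p = 3.83e-09) and 3.17 for TATATTAA (adjusted exact p = 5.89e-06). Against candidates matched on GC content, chosen after seeing the data, TATATTAA did not pass (odds ratio 1.57, adjusted exact p = 0.187) and TTAAAAAA was not among the 10 words. The 4 words that passed there were CACAGTGG (odds ratio 5.09, adjusted exact p = 0.00609), AAAAATGT (2.18, 0.00609), CACTGTGC (3.86, 0.0127) and ACAGTGGG (4.39, 0.0306). Words like CACAGTGG and CACTGTGC had been noticed in peaks of all arms, as described below.

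**Figure D5:**
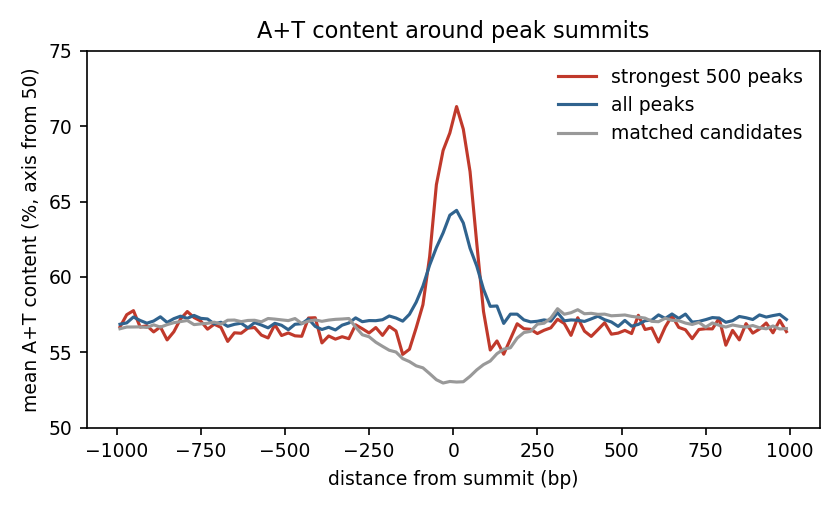
Mean A+T content in 20 bp steps (y axis, percent, starting at 50) by distance from the summit (x axis, bp) for the strongest 500 peaks, all main-list peaks and matched candidates. Peaks rise at the summit and candidates fall.

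Of 13 known consensus motifs, 8 were more frequent and 1 less frequent at Wdn summits than in matched candidates. GATA sites (WGATAA) were in 487 peaks (15.0%) against 8.99% (odds ratio 1.79, adjusted exact p = 5.23e-22), the DRE bound by DREF and BEAF-32 in 45 (1.39%) against 0.474% (odds ratio 2.95, adjusted exact p = 2.75e-07), and Ohler motif 6 in 68 (2.09%) against 0.683% (odds ratio 3.11, adjusted exact p = 6.23e-11). The CTCF core had an odds ratio of 2.14 (adjusted exact p = 0.000339), the TATA box 2.07 (1.56e-05), the su(Hw) core 1.74 (0.0252), Ohler motif 7 1.30 (0.00473) and the BEAF-32 core CGATA 1.23 (0.000584). The E-box CAGCTG was less frequent (odds ratio 0.664, adjusted exact p = 3.45e-05, and odds ratio 0.433 in replicate 2's own list). In the later word search within 200 bp against the peaks' own flanks, AACAGCTG, which holds this E-box, was more frequent on 3L and 3R. It was in 7.90% of peaks against 4.79% of flanks (odds ratio 1.71, adjusted exact p = 5.79e-05). M1BP, GAGA factor, Zelda and initiator motifs did not pass the test, though each did under at least 1 alternative. M1BP did so only as more frequent, against the peaks' own flanks (odds ratio 2.39, adjusted exact p = 0.00604) and within 100 bp (1.66, 0.00362). Zelda and the initiator did so only as less frequent. Zelda was at 0.219 in replicate 1's own list (adjusted exact p = 0.00704) and the initiator at 0.674 in that of replicate 2 (0.000132). The GAGA factor motif passed in both directions, lower in replicate 2's own list (odds ratio 0.536, adjusted exact p = 0.0279) and against the peaks' own flanks (0.637, 0.00604), and higher within 100 bp (1.34, 0.00362). In replicate 1's own list the CTCF core (odds ratio 1.07, adjusted exact p = 0.835), the DRE (1.75, 0.0571), the su(Hw) core (1.67, 0.169) and Ohler motif 7 (1.00, adjusted exact p = 1) did not pass. The su(Hw) core was also lost in replicate 2's own list (odds ratio 1.67, adjusted exact p = 0.0842) and within 100 bp (1.29, 0.160). At an IDR of at most 0.001 the BEAF-32 core (1.16, 0.0698) and Ohler motif 7 (1.28, 0.0619) were lost. A replicate's own list and the stricter IDR leave fewer peaks. Against candidates matched on GC content as well, chosen after seeing the data and possible for 3181 peaks with 1 candidate each, the DRE (odds ratio 2.06, adjusted exact p = 0.0273), CTCF (2.88, 0.00356) and Ohler motif 7 (1.53, 0.00356) stayed past the threshold. GATA (1.05, 0.563), TATA (0.937, 0.787), Ohler motif 6 (1.43, 0.156), the BEAF-32 core (1.07, 0.557) and the E-box (1.19, 0.370) did not, and the GAGA factor motif came past it as higher (1.85, 0.0273). The su(Hw) core kept its odds ratio (1.74) and lost its call (adjusted exact p = 0.216) against this smaller background. No candidate background was matched on position relative to the start, where promoter candidates had a median of 66 bp and promoter peaks of -95 bp. Nor was any matched on the classes outside promoters, and coding exons held 20.6% of all candidates and 1.48% of peaks. With the peaks' own flanks 500 bp away as background, odds ratios fell for GATA (1.25), Ohler motif 6 (2.12) and the TATA box (1.64). They rose there for the DRE (3.50), the CTCF core (2.60) and Ohler motif 7 (1.74). How far these differences in location contribute to the motif results was not tested.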

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

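The overlap and repeat tests below were set before their own results were seen but after the clustering was noticed, and the count of runs, the added list and the scaffold limit were chosen after. A set of peaks that met the IDR threshold of 0.01 in the ranked lists was missing from the thresholded lists, and the comparisons above do not use it as peaks. There were 121 such peaks for the main list, 93 for the conservative list, 78 for replicate 1 and 75 for replicate 2. Being counts above 0 in data that the comparisons leave out flagged them, which is a rule and not a test. They included some of the strongest sites in the data. The strongest, at 481110 on 2L in an intron of ush, had a signal of 1203, and the next were 822 at 11761039 on 3R in an intron of Lk6, 646 at 28326598 on 3R, 334 bp from a start of larp, 458 at 24109190 on 3R near CG18428, and 458 at 14283863 on 3R in an intron of trx. These 5 were chosen by signal after their values were seen. Arm 3R held 59 of the 121, X held 2 and other scaffolds 8 (6.61%, against 6 of the 3254 listed peaks, 0.184%).

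The missing peaks were clustered. Those on the main chromosomes, 113 in number, fell into 51 runs with no listed peak between their members, against a median of 110 runs and a lowest of 101 in 1000 random draws. The longest run held 9 peaks between 7241743 and 7249688 on 2R. A candidate explanation is the removal of fixed regions in the authors' filtering: only 1 of the 121 (0.826%) overlapped a peak of any thresholded list, while 104 (86.0%) overlapped a passing peak of another ranked list. Soft-masked repeats in the reference were argued against as the cause for the set as a whole. On the main chromosomes the soft-masked share of the 113 missing peaks was below that of listed peaks (-1.81 ± 1.26 percentage points, standard error). Counting the 8 scaffold peaks as fully masked gave 3.72 ± 2.22, where over 10 was predicted. For the scaffold peaks themselves this cause stays open, since their masking was not measured. Repeated sequence that is not soft-masked was not measured and stays open too. Whether regions were removed, and on what grounds, stays open, and no biological explanation was tested since the series has 1 group. Adding the 121 peaks to the main list gave 3375 peaks, with a promoter share of 52.2% over the 3361 that are not on scaffolds, and the deficit of 3R was then not past the threshold (odds ratio 0.940, Fisher's exact test, adjusted p = 0.336).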

How the results depend on the processing

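Settings with an IDR of at most 0.001, GC-matched backgrounds, assignment to the nearest start and added missing peaks were chosen after seeing the data. The promoter share kept its direction and its side of the threshold under all alternatives run, between 39.3% with a 200 bp window and 63.9% with a 1000 bp window. The replicate overlap did so too (58.2 to 68.5% for replicate 1 and 64.7 to 69.4% for replicate 2), as did the ribosomal protein, cuticle, receptor and tRNA lists. An IDR of 0.01 removed no peak and says nothing about stability. The number of peaks was 1796 to 1996 without either replicate and 1694 at an IDR of at most 0.001, both by construction. The rho of 0.32 over all shared ranked peaks includes weak peaks. The number of gene lists past the threshold fell from 8 to between 4 and 5 without either replicate and to 5 at the stricter IDR, which leave fewer bound genes. With GC-matched candidates, 4 motifs and 4 of 10 words passed. The other odds ratios that crossed 1 follow, and the cause was not tested. With the conservative list these were other exons (0.868), chromosome 4 (1.28), dorsoventral regulators (0.902), glia (0.547) and muscle markers (1.15) and M1BP (0.930). At the stricter IDR they were chromosome 4 (1.37), neuron (1.11) and glia markers (0.856). Dorsoventral regulators fell to 0.266 with a 200 bp and 0.921 with a 1000 bp window. Muscle markers were at 1.18 against all annotated genes. Other exons were at 0.926 against random positions and X at 0.975 with missing peaks added. With nearest starts, initiation factors were at 0.917, segmentation genes at 1.20 and muscle markers at 1.42. The GAGA motif was at 1.06 with missing peaks added and rose to 1.34 within 100 bp and 1.85 with GC matching, where the E-box was at 1.19 and the TATA box at 0.937. Without either replicate the ranges were 0.946 to 1.01 for 3L, 0.674 to 0.696 for dorsoventral regulators, 0.662 to 2.25 for glia, 0.642 to 1.05 for muscle, 0.441 to 1.12 for neuron markers, 0.275 to 1.07 for segmentation genes, 0.964 to 1.28 for oxidative phosphorylation, 0.809 to 1.47 for synthetases and 0.536 to 1.28 for GAGA. None of these was past the threshold both in the main result and in the alternative. Read depth was not known, so its effect on the number of peaks was not measured.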

Other observations

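Apart from the repeat test of the CACTGTG word, the tests here were chosen after seeing the data. Wdn peaks at promoters often lay between diverging starts. Of 1705 promoter summits, 527 (30.9%, 28.7 to 33.2%) had a minus-strand start to the left and a plus-strand start to the right within 500 bp, against 5.18% of candidates at promoters (odds ratio 8.19, Fisher's exact test, p = 1.05e-213). Among the promoter summits of the strongest 500 peaks the share was 35.5% (30.4 to 40.9%). A summit between such starts lies upstream of both, and 77.8% of promoter summits but 40.9% of candidates at promoters were upstream of the nearest start. Part of the excess between diverging starts can therefore restate that position, and upstream summits were not compared alone. Cytosolic ribosomal protein genes differed from the 5 other housekeeping lists combined, which were bound in 52 of 238 cases (21.8%, 16.8 to 27.6%; odds ratio 6.92, Fisher's exact test, p = 3.50e-13). Transposable elements held few peaks, with 6 summits in annotated copies (0.185%) against 0.956% of candidates (odds ratio 0.192, Fisher's exact test, p = 9.82e-08). The 1543 summits outside promoters had a median distance of 2058 bp to the nearest start, and candidates outside promoters 3435 bp.

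The A and T richness of summits was weighed against base composition. A bias of the libraries toward A and T was predicted to raise candidates of the same libraries too. Their summits were below their flanks by 4.19 percentage points (-4.19 ± 0.0946, standard error). Candidates also differ in where they lie, with 20.6% in coding exons against 1.48% of peaks and 13.8% of random positions. How far location sets their A+T content was not measured, so their fall cannot decide on a bias at the peaks. Promoter composition alone was argued against by the peaks outside promoters, which rose by 4.99 ± 0.326 percentage points. A bias that acts on the strongest sites alone also stays open without the control library.

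A second sequence lay around the summits. Within 200 bp, the words CACAGTGG and CACTGTGC ranked highest on X, 2L and 2R against the peaks' own flanks. Words of this kind had first been noticed among the strongest 500 peaks of all arms, so 3L and 3R were not unseen data for them. On 3L and 3R they were in 6.78% of 1430 peaks against 1.99% of flanks (odds ratio 3.58, adjusted exact p = 6.96e-14) and in 6.22% against 1.64% (odds ratio 3.97, adjusted exact p = 6.54e-14). The DRE word TATCGATA ranked next (odds ratio 4.34, adjusted exact p = 5.14e-14). The shared core CACTGTG was within 200 bp of 167 of the 1430 summits (11.7%, 10.1 to 13.5%) and of 5.21% of candidates (odds ratio 2.40, Fisher's exact test, p = 1.90e-17).

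Base composition around peaks was argued against as the source of the CACTGTG excess, since 630 words of the same bases had a median odds ratio of 0.904 on 3L and 3R, with 95% of them at or below 1.49, against 2.49 for the word. It ranked 1, closely followed by CACTGAG (2.39). That rank uses peaks in which the word was noticed; outside the strongest 500 it ranked 3, at 2.28 against 2.46 for CACTGAG, with a median of 0.916. Copies of a soft-masked repeated element were argued against too: the soft-masked share of the word was 0.508% within 200 bp and 1.46% beyond 500 and up to 1000 bp, a difference of -0.956 ± 0.980 percentage points. Repeats that are not soft-masked were not measured. The hypothesis that the word lies beside the A/T-rich centre rather than at it could not be decided. Its density 51 to 200 bp from the summit was 1.17 times that within 50 bp (153 and 44 occurrences, exact binomial p = 0.412), and the densities were 0.357 and 0.305 per kb against 0.143 per kb beyond 500 and up to 1000 bp. Within 50 bp, 2 words that hold the core were in excess on 3L and 3R against GC-matched candidates. These were CACAGTGG (1.44% against 0.286%, odds ratio 5.09, adjusted exact p = 0.00609) and CACTGTGC (1.37% against 0.357%, 3.86, 0.0127). The word was thus not confined to the sides, though these peaks too were not unseen data. In narrower steps, not tested, the density of the core was 0.517 per kb 51 to 100 bp away and 0.238 per kb 151 to 200 bp away. Among the 209 of the strongest 500 peaks that lie on 3L and 3R, part of the set in which such words were first noticed, it was 0.189 per kb within 50 bp (4 occurrences), 1.00 at 51 to 100 bp (21) and 0.718 at 101 to 150 bp (15).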
